A study of Mus musculus with 57 samples.

How the data were processed

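Lungs were perfused with cold saline, frozen, and extracted with TRIzol followed by a column clean-up, per the labels' protocols. RNA with an integrity number over 7 was used, 200 ng went into each library, and libraries were sequenced as paired 100 bp reads on DNA nanoballs, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.7, STAR 2.7.6a and a second version of STAR, Salmon, and the genome builds GRCm39 and GRCh38, without saying which step each served. The annotation, the strand setting and which of these tools, if any, counted the reads are not given in the sources used here.

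Each sample was placed in 1 of 12 groups from its title, which gives the time point, the age and a replicate number. The deposited table has 57 columns of per-sample values. Each column name was compared with every title, description, source name and characteristic of the 57 samples. No column name equalled a label of exactly 1 sample. The names of 10 columns equalled the running number that the labels restart at each time point, and each of those fitted between 3 and 6 samples. The names of the other 47 columns equalled no label. All 57 columns were therefore left unused. Neither the order of the columns nor the values in them was used to assign samples, since an error there would exchange ages or times of day in every result.

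Before the data were examined, tests had been fixed for the age difference over the day and at each time point, for a daily rhythm in each age, for the difference in rhythm, and for lists of clock, pathway and cell type marker genes. None of these tests was run, so no depth, expression value, error or p-value is reported.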

Results

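The series measured messenger RNA in the lungs of male C57BL/6J mice, the standard inbred laboratory strain, at 2 ages and 6 times of day, by sequencing of polyadenylated RNA. Time was counted from the onset of light (zeitgeber time, ZT), with lights off at ZT12. There were 57 samples in 12 groups of age and time. Young mice gave 5 samples at each of the 6 time points, 30 in all. Old mice gave 5 samples at each of ZT0, ZT4 and ZT8 and 4 at each of ZT12, ZT16 and ZT20, 27 in all. Sampling was every 4 h. Young mice were 2 months old. The age of the old mice was given as 22 months in the design text of the series and as 18 months in the description of the animals' housing, and no other label settled which applied. The design text ran the sampling to ZT24, whereas the last samples were from ZT20.

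The design implied the following comparisons. Old and young lungs could be compared over the whole day and at each time point. The daily rhythm could be examined within each age, and its timing and strength could be compared between ages. None of these comparisons was made. The table of expression values named its columns only by running number, and no label tied a number to one mouse, age or time of day. No gene, cell type marker or clock component is therefore reported as higher, lower, rhythmic or unaltered in either age.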

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

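No paired analysis was possible because the columns of values carry no replicate number that the labels tie to a sample. The replicate number in a title counts the samples within its group of age and time. The titles do not say that samples sharing a number in different groups belong together. Even with every column identified, these numbers alone would therefore not have defined pairs. The unidentified columns were thus not the only obstacle to a paired analysis. None of the alternatives planned before the data were examined was run, since no comparison between groups was made. The number of columns that the labels identify was recounted under 2 looser rules, chosen after the column names were seen. With a column name allowed to equal any number standing in a title, or any number standing in any label, 0 of the 57 columns fitted exactly 1 sample, as under the main rule. The title rule could not have come out otherwise, because every number in the titles is shared by several samples.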
